A study of Mus musculus with 15 samples.

How the data were processed

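The deposited table of gene-level FPKM values of the 12 skin libraries was used as the authors supplied it. Per the submitters' processing notes, reads were aligned to the mouse genome mm10 and counted per gene with featureCounts. The aligner version, the annotation release and the tool that computed FPKM are not given in the sources used here. The libraries were described as poly-A RNA with random hexamer priming, and the strand was not used. The series describes 15 samples, and the 3 dorsal root ganglion samples were not analysed here.

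The table held 54532 genes. Multiplying FPKM by gene length gave whole reads, after scaling by a factor per library, for 100% of the values within a tolerance of 0.01. The recovered totals were 16869716 to 18485698 reads per library. The implied denominators were 0.917 to 1.115 times those totals and followed median-of-ratios size factors with a largest deviation of 0.57%. The deposited values were therefore taken as already scaled between libraries. Of the gene identifiers 54409 were found in the mm10 reference used for coordinates, and 53499 had the same start and end.

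Genes were kept when FPKM was at least 0.5 in at least 3 libraries, which left 17646. Linear models were fitted with limma to log2(FPKM + 0.5) over the 4 groups, leaving 8 residual degrees of freedom, and variances were moderated with eBayes and a mean trend. The contrasts were MC903 against untreated in each genotype, the genotypes against each other in untreated and in MC903 skin, and the difference of the MC903 response between genotypes. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each contrast, and the threshold was an adjusted p of 0.05. All adjusted p-values of genes in these texts come from limma.

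Gene lists with at least 3 measured members, 38 in number, were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated for each list, adjusted over the lists within each contrast. For single members the adjustment was also made over the list alone. Sizes of response were compared on genes with an adjusted p below 0.05 for the mean MC903 effect over both genotypes, with signs given by that mean effect. Each library was scored by the mean over these genes, and exact two-sided permutation tests over 20 assignments compared the genotypes. The MC903 responses of the genotypes share no libraries.

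The axis genes were named in every contrast. Further named genes were the 10 highest and 10 lowest log2 fold changes among passing genes with groups that did not overlap, a mean FPKM of at least 1 in the higher group and a name that was not a predicted one, and up to 4 members of each list by adjusted p. A gene that this rule names is not reported here. Lce1m, Flg2 and Acan were named after their values were seen, as were the values of Gsdmc within each genotype and of Kit after MC903 in skin labelled knockout. The contrasts, tests, thresholds, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were other pseudocounts, filters, scalings between libraries, robust variance moderation, library weights, limma voom on the recovered reads, replicate number as a block, fits of only the groups compared, a 2-fold threshold and leaving out each library in turn. Scaling by total reads and a fit of protein-coding genes of at least 200 bp were added after the data had been seen.

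The procedure was tested on simulated data with 100 changed genes per contrast and size of change. Of 2-fold changes 87% to 94% were recovered and of 4-fold changes 96% to 100%, with 8 to 15 false calls. The simulation used the same dispersion, 0.0066, for every contrast, whereas the spread between real replicates differed between groups. It also changed far fewer genes than the 2064 to 11109 that passed per contrast in the skin data. These rates therefore describe the simulated setting and do not give the recovery or the false calls in the skin data. A simulated response ratio of 0.6 was recovered as 0.62. Replicates of a group differed by more than the sampling of reads, with a chi-square per degree of freedom of 6.5 to 60.1. Of the variance between libraries the leading principal components held 58.3%, 17.3% and 6.94%.

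R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.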

Results

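Skin RNA was profiled in mice labelled wild type or Trpv3 knockout, each either left untreated or given MC903 for 7 days. MC903 (calcipotriol) is a vitamin D analogue that, applied to mouse skin, gives an inflammation used as a model of atopic dermatitis. Each of the 4 groups held 3 libraries of poly-A RNA, and a library of skin mixes RNA of epidermis, hair follicles, glands, dermis, fat, muscle, nerve and immune cells. The series concerns TRPV3, a heat-activated calcium-permeable channel of keratinocytes, PAR2 (gene F2rl1), a receptor switched on by serine proteases, the epithelial alarmin IL-33, and mast cells. Between 16869716 and 18485698 reads per library were assigned to genes, and 23281 to 24927 genes had an FPKM above 0. At that depth 1 read on a gene of 1 kb was worth an FPKM of 0.0496 to 0.0615. Levels are the mean FPKM ± SD of the 3 libraries of a group, and log2 fold changes are on the log2(FPKM + 0.5) scale with their standard error (SE), which understates the change of genes with low levels. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

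The targeted gene was read in every library to check the labels. Trpv3 (ENSMUSG00000043029, chromosome 11, 73267388 to 73300363 of mm10) had an FPKM of 2.06, 2.71 and 1.13 in untreated wild type replicates 1, 2 and 3, and of 3.17, 3.64 and 2.62 in the untreated replicates labelled knockout. After MC903 it read 16.1, 17 and 19 in wild type and 6.82, 6.78 and 4.73 in the libraries labelled knockout, which held 511 to 722 reads of the gene. Trpv3 RNA was thus not lower in untreated libraries labelled knockout (log2 fold change 0.61 ± 0.22 SE, limma adjusted p = 0.1), and it was lower after MC903 (-1.45 ± 0.22, limma adjusted p = 0.00032). Of 8 basal keratinocyte markers 7 were lower in that MC903 comparison as well (median -1.16). The lower Trpv3 there therefore does not by itself bear out the labels. Without untreated wild type replicate 2 the untreated difference passed the threshold, with higher Trpv3 in the libraries labelled knockout (0.83, limma adjusted p = 0.046), as it did with library weights (0.52, limma adjusted p = 0.01). These are sums over all exons of the gene, so they neither show nor exclude the loss of part of it. The series speaks of conditional knockouts and the labels do not say which cells lose the gene, so RNA of whole skin also includes Trpv3 of cells that keep it. The genotype is given here as the labels give it. Among male-specific genes Ddx3y ranged from 15.8 to 28.1 FPKM over the 12 libraries, and Xist, which is transcribed from the inactive X chromosome, did not exceed 0.02.

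**Figure D1:**
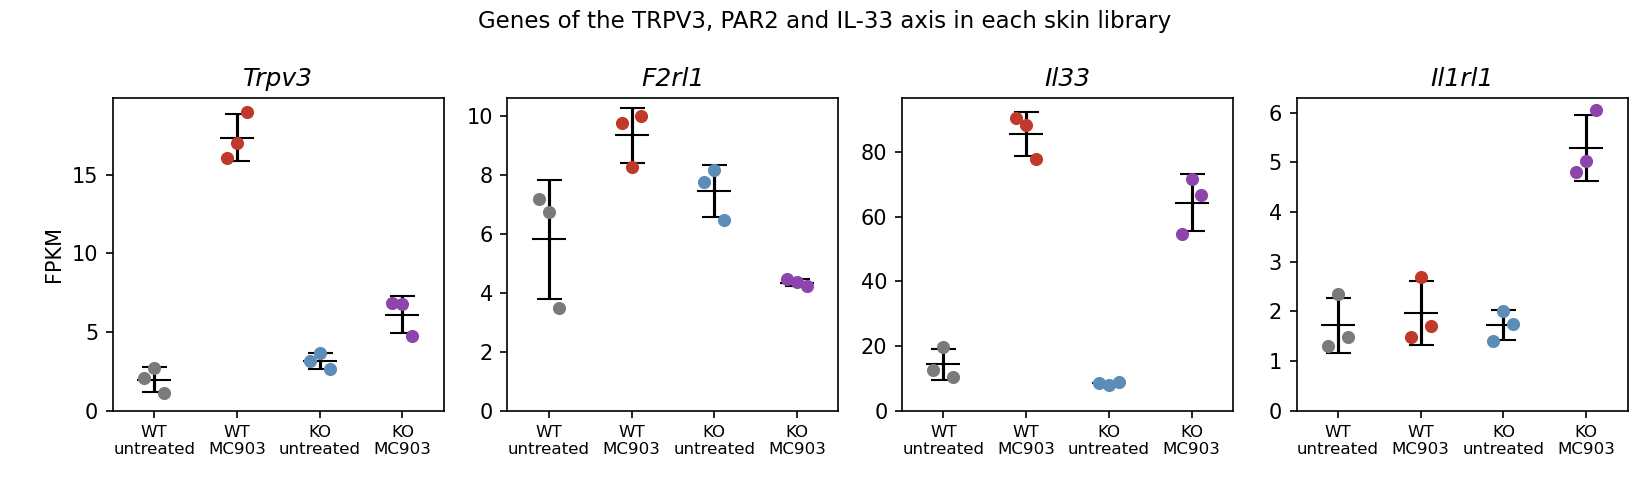
FPKM of Trpv3, F2rl1, Il33 and Il1rl1 (vertical axes, each from 0) in the 4 groups of skin libraries; points are the 3 libraries of a group, horizontal lines the mean and error bars the SD. Trpv3 sits at 16.1 to 19 in wild type MC903 libraries and at 4.73 to 6.82 in MC903 libraries labelled knockout, and Il1rl1 is highest in the latter.

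The comparison of MC903 with untreated wild type skin asked what the treatment does when the channel is intact. After MC903 the RNA of genes of an inflamed and dividing epidermis was higher, and that of genes of nerve, fat and dermal matrix lower. RNA of whole skin does not separate a change within cells from a changed share of a tissue. The labels name no vehicle for the untreated libraries, so effects of a vehicle or of handling cannot be told apart from those of MC903. Cyp24a1, the enzyme that breaks down vitamin D and a direct target of its receptor, went from 0.00464 ± 0.00804 to 1820 ± 344 FPKM (n = 3 per group). Krt6b and Krt16, keratins of wounded and hyperproliferative epidermis, went from 1.07 ± 0.774 and 3.81 ± 2.57 to 3240 ± 677 and 5260 ± 1130. Their log2 fold changes were 11.13 ± 0.46 and 10.46 ± 0.51 (limma adjusted p = 1.7e-08 and 4.3e-08). The alarmin Tslp rose from 1.51 ± 0.477 to 332 ± 188 (7.26 ± 0.33, limma adjusted p = 3e-08). Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718) rose 6.01-fold, from 14.3 ± 4.82 to 85.7 ± 6.83 (2.59 ± 0.19, limma adjusted p = 6.1e-07), and Trpv3 itself 7.5-fold (2.91 ± 0.22, limma adjusted p = 9.5e-07). F2rl1 (ENSMUSG00000021678, chromosome 13, 95511732 to 95525227) went from 5.81 ± 2.02 to 9.35 ± 0.936 (0.7 ± 0.21, limma adjusted p = 0.012). Without untreated wild type replicate 3, which stood at 3.49 against 7.19 and 6.75 in replicates 1 and 2, the log2 fold change of F2rl1 was 0.4, and it was 0.39 with library weights. The call ended when libraries were scaled to TPM or by total reads and when only these 2 groups were fitted (limma adjusted p of up to 0.35). Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415), which encodes the IL-33 receptor ST2, did not pass, at 1.71 ± 0.562 against 1.97 ± 0.64 (limma adjusted p = 0.54).

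Of 17646 genes tested, 11109 passed in this comparison, 5758 higher and 5351 lower after MC903, and 4200 of them by at least 2-fold. Gene lists fixed beforehand are given with the number of measured members that rose or fell over all genes tested, which equals the number adjusted over the list alone except where that is stated. All 27 measured stress keratin and inflamed-epidermis genes rose (median log2 fold change 8.21), as did all 24 cell cycle genes (2.06). Among the latter Mcm5 went from 3.31 ± 0.333 to 22 ± 3.1 and Cdk1 from 2.33 ± 0.653 to 12.4 ± 0.902. Of the late cornified envelope genes, which build the outermost keratinocyte layer, 19 of 20 rose and Lce1m fell, and of the terminal differentiation genes 15 of 21 rose and Flg2 fell. Among skin proteases and their inhibitors 12 of 13 rose (median 2.83), with Klk6 going from 1.75 ± 1 to 754 ± 88 and Klk13 from 0.669 ± 0.444 to 286 ± 26. Among genes related to IL-1, IL-36 and IL-17 15 of 18 rose, including the neutrophil attractants Cxcl3, listed at 0 in all 3 untreated libraries and at 3.14 ± 0.659 after MC903, and Cxcl5. The camera test with a preset correlation gave these 6 lists adjusted p-values of 3.2e-15, 6.9e-10, 1e-07, 2.5e-05, 3.4e-06 and 8.5e-06 in that order, and each had an adjusted p = 0.42 with an estimated correlation. All 5 vitamin D response genes rose (adjusted p = 0.0056, and adjusted p = 0.42 with an estimated correlation). Of 13 immediate early and heat shock genes 8 rose and 1 fell (median 0.72; adjusted p = 0.05, just under the threshold, and adjusted p = 0.52 with an estimated correlation), a call that ended in many alternatives (adjusted p of up to 0.075). The Stfa, Sprr2 and Lce genes form families of near-identical copies, so the share of reads given to any 1 member is uncertain.

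Immune genes moved in both directions in wild type skin. Of 8 neutrophil markers 6 rose, such as the receptors Cxcr2, from 0.43 ± 0.109 to 8.83 ± 1.94, and Csf3r (list adjusted p = 0.0052, and adjusted p = 0.42 with an estimated correlation). Of 15 type 2 genes 9 rose and 2 fell (list adjusted p = 0.025, and adjusted p = 0.42 with an estimated correlation). Arg1, an enzyme of type 2 macrophages, went from 1.42 ± 0.276 to 171 ± 52.5 and the interleukin 4 receptor Il4ra from 4.93 ± 1.02 to 43.7 ± 4.31. Of 18 interferon response genes 15 rose and 2 fell (list adjusted p = 0.0029, and adjusted p = 0.57 with an estimated correlation). Mast cell markers did not pass as a list (adjusted p = 0.058), yet 8 of 13 fell and 2 rose. The growth factor receptor Kit went from 4.03 ± 0.769 to 1.49 ± 0.216 (-1.17 ± 0.13, limma adjusted p = 1.4e-05), and the receptor Mrgprb1 from 5.4 ± 1.4 to 2.29 ± 0.211. Hdc, the histamine-making enzyme also found in other myeloid cells, rose from 1.37 ± 0.266 to 9.81 ± 3.02, and the basophil protease Mcpt8 from 0.0674 ± 0.0277 to 12.4 ± 1.44 (4.51 ± 0.15, limma adjusted p = 4e-09).

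All 10 Schwann cell and nerve markers fell after MC903 in wild type skin (median -2). Of the 97 list calls made with a preset correlation over the 5 comparisons, this was the only one to hold with an estimated correlation (adjusted p = 3.9e-07 and 0.036). Of 15 fibroblast and matrix genes 14 fell and Tnc, a matrix protein of wounds, rose; Dcn went from 570 ± 125 to 177 ± 15.7. Of 14 adipocyte markers 12 fell and 1 rose, with the lipid droplet coat Plin1 going from 61.7 ± 14.9 to 5.58 ± 1.64, and of 14 sebaceous gland genes 8 fell and 1 rose. Of 13 genes of the mitochondrial genome 9 fell. These 4 lists had preset adjusted p-values of 0.0006, 0.00052, 0.011 and 0.002, and an adjusted p = 0.51 for the first and 0.42 for the others with an estimated correlation. Outside the lists the largest falls included the defensin Defb8, from 43.5 ± 22.4 to 0.0694 ± 0.12, and the Wnt inhibitor Wif1, from 602 ± 109 to 39.7 ± 1.58. Scaling to TPM moved the median of all genes by -0.43 and left 26.7% of the called genes higher, against 51.8% as deposited. Scaling by total reads moved it by -0.17 and left 40% higher, so the sign of small changes depended on the scaling.

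The same comparison in skin labelled knockout asked whether MC903 acts alike there. Cyp24a1 was listed at 0 in all 3 untreated libraries and stood at 1380 ± 354 FPKM after MC903. Krt6b rose from 4.36 ± 2.47 to 966 ± 199 (7.79 ± 0.46, limma adjusted p = 5.6e-07). Tslp rose from 1.72 ± 0.353 to 389 ± 98.2 (7.44 ± 0.33, limma adjusted p = 8e-08), and Il33 7.17-fold, from 8.49 ± 0.44 to 64.4 ± 8.83 (2.84 ± 0.19, limma adjusted p = 1.1e-06). Mcpt8 rose to 62.1 ± 9.38 (6.74 ± 0.15, limma adjusted p = 6.3e-10), and the mast cell and basophil receptor chain Fcer1a from 0.948 ± 0.454 to 18.5 ± 5.46 (3.72 ± 0.24, limma adjusted p = 9.2e-07). Trpv3 rose 1.8-fold (0.85 ± 0.22, limma adjusted p = 0.0089) and Il1rl1 from 1.72 ± 0.307 to 5.29 ± 0.668 (1.38 ± 0.21, limma adjusted p = 0.00031). F2rl1 fell from 7.46 ± 0.883 to 4.35 ± 0.123 (-0.71 ± 0.21, limma adjusted p = 0.015), a call that ended without untreated replicate 2 labelled knockout (limma adjusted p = 0.052).

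In this comparison 8457 genes passed, 4406 higher and 4051 lower, 2283 of them by at least 2-fold. Of the stress keratin and inflamed-epidermis genes 24 of 27 rose and 1 fell (25 and 1 adjusted over the list alone; median 5.89), and all 24 cell cycle genes rose (1.2). All 6 basophil markers rose (median 2.86), as did 7 of 8 neutrophil markers (3.45) and 12 of 13 monocyte and macrophage markers (1.26). The basophil protease Prss34 went from 0.0568 ± 0.0641 to 14.4 ± 1.59 and the mannose receptor Mrc1 from 33.2 ± 1.45 to 150 ± 27. Preset adjusted p-values of these 5 lists were 7.7e-16, 1.1e-09, 1.7e-05, 1.3e-05 and 1.7e-05, against adjusted p-values of 0.17, 0.32, 0.087, 0.087 and 0.23 with an estimated correlation. Of 13 mast cell markers 7 rose and 1 fell (8 and 2 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.52 with an estimated correlation). Ms4a2, a chain of the IgE receptor, went from 4.28 ± 0.191 to 12.9 ± 3.44. The mast cell and basophil lists share Fcer1a and Cpa3 in every comparison. Their counts are therefore not independent, and the mast cell list does not fully separate mast cells from basophils. Of 17 skeletal muscle markers 16 fell, such as the fast-fibre gene Actn3 from 45 ± 7.7 to 6.05 ± 1.08 (list adjusted p = 5.2e-07, and adjusted p = 0.39 with an estimated correlation). Of 10 Schwann cell and nerve markers 8 fell (adjusted p = 3e-05, and adjusted p = 0.087 with an estimated correlation). Among genes related to IL-1, IL-36 and IL-17 12 of 18 rose and 2 fell (12 and 3 adjusted over the list alone). Of 18 interferon response genes 10 rose, and of 15 type 2 genes 10 rose and 4 fell. Preset adjusted p-values were 3.9e-05, 0.007 and 0.016, against 0.25, 0.65 and 0.15 with an estimated correlation. These lists did not pass for the difference of response between genotypes (preset camera adjusted p = 0.68, 0.14 and 0.44). The suprabasal keratin Krt77 fell from 62 ± 12.4 to 2.48 ± 1.65 (-4.51 ± 0.41, limma adjusted p = 1e-05). Hair shaft keratins such as Krt27 and Krt71 were also among the largest falls, on replicates that differed widely within a group (39.9 ± 24.1 and 62.3 ± 32.1 untreated), and of the hair list 19 of 28 genes fell and 6 rose (median -2.54), which did not pass as a list (adjusted p = 0.14). In wild type 2 hair genes fell and 8 rose after MC903 (median -0.84, list adjusted p = 0.78). Without untreated wild type replicate 3, 14 fell and 7 rose there (median -1.6, list adjusted p = 0.3). Of 16 keratin-associated protein genes 7 fell and 1 rose (adjusted p = 0.042, and adjusted p = 0.66 with an estimated correlation). The call of Krt71 (limma adjusted p = 0.046) ended in 11 of 26 alternatives (limma adjusted p of up to 0.16) and that of Krt27 (limma adjusted p = 0.014) in 2. Scaling to TPM moved the median of all genes by -0.18 and left 33.5% of the called genes higher, against 52.1% as deposited.

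The comparison of skin labelled knockout with wild type without treatment asked what the genotype does at rest. Matrix genes were higher in the libraries labelled knockout. Col1a2, a chain of the main collagen of dermis, stood at 898 ± 79.4 FPKM against 207 ± 77.7 (2.18 ± 0.24, limma adjusted p = 0.00095) and Col3a1 at 1310 ± 111 against 275 ± 96.3 (2.31 ± 0.23, limma adjusted p = 0.00074). Tnc stood at 22.8 ± 1.45 against 7.13 ± 0.0803 (1.61 ± 0.1, limma adjusted p = 5.6e-05). Genes of inflamed and cornifying epidermis were higher too. Stfa3, a protease inhibitor, stood at 52.2 ± 8.51 against 4.56 ± 2.01 (3.44 ± 0.25, limma adjusted p = 0.00021) and the attractant Ccl20 at 6.14 ± 1.88 against 0.366 ± 0.294 (2.95 ± 0.32, limma adjusted p = 0.00091). The IL-36 cytokine Il1f6 stood at 28.5 ± 3.06 against 4.27 ± 2.11 (2.72 ± 0.36, limma adjusted p = 0.002). The fat hormone Lep was lower, at 7.79 ± 0.917 against 32.3 ± 8.44 (-1.96 ± 0.23, limma adjusted p = 0.001). So were Tnnc1, a calcium sensor of slow muscle fibres, at 4.04 ± 0.922 against 21.4 ± 5.19 (-2.26 ± 0.24, limma adjusted p = 0.0008), and Fcer1a (-1.66 ± 0.24, limma adjusted p = 0.0028). Il33 was 1.59-fold lower (-0.67 ± 0.19, limma adjusted p = 0.041), a call that ended in many alternatives, with a limma adjusted p of up to 0.14. F2rl1 and Il1rl1 did not pass (limma adjusted p = 0.25 and 0.95).

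Here 2064 genes passed, 1261 higher and 803 lower, 441 of them by at least 2-fold. Of 20 late cornified envelope genes 16 were higher (20 adjusted over the list alone; median 1.27), and of 27 stress keratin and inflamed-epidermis genes 18 (21 adjusted over the list alone; 1.45). So were 12 of 21 terminal differentiation genes (16 adjusted over the list alone; 1.23), 11 of 15 fibroblast and matrix genes (12 adjusted over the list alone; 1.18) and 7 of 11 dendritic and Langerhans cell markers (8 adjusted over the list alone; 0.57). Lower were 9 of 13 mitochondrially encoded genes (12 adjusted over the list alone; -1.02) and 10 of 14 adipocyte markers (-0.84). Preset adjusted p-values were 1.2e-12, 1.2e-12, 1.8e-09, 1.2e-12, 2.6e-05, 1.4e-11 and 1e-07, and with an estimated correlation the adjusted p-values were 0.21, 0.21, 0.26, 0.21, 0.21, 0.21 and 0.23. Mast cell markers did not pass as a list (adjusted p = 0.5). Immediate early and heat shock genes, which respond quickly to handling of tissue, moved with the epidermal genes. Of these 6 of 13 were higher (8 adjusted over the list alone; adjusted p = 1.6e-05, and adjusted p = 0.21 with an estimated correlation), Fosb at 7.4 ± 4.05 against 1.26 ± 0.543, a call that ended in 3 alternatives (limma adjusted p of up to 0.078). Of the hair follicle and shaft genes 2 of 28 were higher (median 1.5; list adjusted p = 0.00046, and adjusted p = 0.59 with an estimated correlation). The mean level of this list was -0.39 in untreated wild type replicate 3 against 1.77 and 2.7 in replicates 1 and 2, and without replicate 3 the median was 0.51 and the list did not pass (adjusted p = 0.4). The number of genes that passed depended on single libraries, with 3562 without that library, 1149 without untreated wild type replicate 2, and 831, 752 and 1176 without untreated replicates 1, 2 and 3 labelled knockout. It was 613 when only these 2 groups were fitted and 6548 with library weights, and the share of higher genes went from 61.1% to 48.6% with quantile normalization and to 49.7% with scaling by total reads.

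The comparison of genotypes after MC903 asked how the treated skin differs when Trpv3 is labelled as lost. Markers of mast cells and basophils were higher in the libraries labelled knockout. The mast cell proteases Cpa3 and Mcpt4 stood at 94.9 ± 7.33 and 162 ± 10.6 FPKM against 28.8 ± 2.48 and 66.2 ± 4.74 in wild type (1.71 ± 0.13 and 1.28 ± 0.13, limma adjusted p = 4.1e-06 and 2.2e-05). Kit stood at 5.41 ± 0.353 against 1.49 ± 0.216 (1.57 ± 0.13, limma adjusted p = 5.8e-06), and Prss34 at 14.4 ± 1.59 against 0.509 ± 0.293 (3.92 ± 0.2, limma adjusted p = 1.1e-06). Il1rl1 was 2.39-fold higher (1.26 ± 0.21, limma adjusted p = 0.00052) and its co-receptor Il1rap 2-fold (1 ± 0.13, limma adjusted p = 8e-05). F2rl1 was 2.03-fold lower (-1.02 ± 0.21, limma adjusted p = 0.0018), as was the differentiation protein Lor (loricrin), at 212 ± 80.4 against 960 ± 315 (-2.19 ± 0.35, limma adjusted p = 0.00039). Il33 did not pass, at 64.4 ± 8.83 against 85.7 ± 6.83 (limma adjusted p = 0.082), although it passed as lower in 5 alternatives (limma adjusted p down to 0.011). The chitinase-like protein Chil4, made in type 2 inflammation, was lower at 2.06 ± 0.81 against 43.6 ± 16.6 (-4.09 ± 0.28, limma adjusted p = 2.7e-06). It did not stand for its list, as 5 of 15 type 2 genes were higher and 2 lower (median 0.25). That list did not pass (camera adjusted p = 0.57, and adjusted p = 0.71 with an estimated correlation).

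After MC903 9187 genes differed between genotypes, 4575 higher and 4612 lower in the libraries labelled knockout, 2489 of them by at least 2-fold. Of 13 mast cell markers 10 were higher (median 1.13), of 6 basophil markers 5 (1.83), and of 8 neutrophil markers 7 (1.47). So were 11 of 13 monocyte and macrophage markers (12 adjusted over the list alone; 1.45), such as Csf1r at 71.9 ± 11.7 against 21 ± 0.79, and all 11 dendritic and Langerhans cell markers (0.95). Markers of resident dermal cells moved with them: all 15 fibroblast and matrix genes (1.73), 10 of 12 endothelial markers, with 1 lower (0.99), all 10 Schwann cell and nerve markers (0.96) and all 7 melanocyte markers (0.85) were higher. Preset adjusted p-values of these 9 lists were 8.7e-05, 0.00051, 0.0011, 2.9e-05, 6.9e-05, 1.3e-07, 0.00092, 3.9e-05 and 0.0032, against adjusted p-values of 0.45, 0.33, 0.33, 0.33, 0.33, 0.4, 0.5, 0.1 and 0.33 with an estimated correlation. All 5 erythrocyte genes, which follow the blood content of a sample, were higher too (1.78; adjusted p = 0.041, and adjusted p = 0.68 with an estimated correlation), a call that ended without any of several single libraries (adjusted p of up to 0.085). All 17 skeletal muscle markers were lower (-1.67, list adjusted p = 7.2e-06, and adjusted p = 0.5 with an estimated correlation), such as Tnni2 at 64.6 ± 19 against 296 ± 38.6. The fibroblast, melanocyte and dendritic cell lists had also passed as higher in untreated skin labelled knockout (medians 1.18, 0.73 and 0.57). Their difference of response between genotypes did not pass (preset camera adjusted p = 0.051, 0.33 and 0.065). The macrophage and neutrophil lists were higher untreated as well (0.56 and 0.48) but passed for that difference.

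Epidermal genes were lower in MC903 skin labelled knockout than in MC903 wild type skin. Of 8 basal keratinocyte markers 7 were lower (median -1.16), such as Krt5 at 559 ± 81.9 against 2050 ± 512 and Krt15 at 33.5 ± 6.04 against 160 ± 38.5. So were 14 of 21 terminal differentiation genes (-0.93), 9 of 13 proteases and inhibitors (-0.78) and 14 of 24 cell cycle genes (-0.41). St14, a protease that matures other proteases, stood at 5.29 ± 0.852 against 12.8 ± 1.37. Preset adjusted p-values of these 4 lists were 0.00054, 0.00034, 0.0067 and 0.0032, and with an estimated correlation the adjusted p-values were 0.49, 0.62, 0.68 and 0.71. Of the stress keratin and inflamed-epidermis genes 14 of 27 were lower and 2 higher (adjusted p = 0.023, and adjusted p = 0.71 with an estimated correlation), and without MC903 replicate 3 labelled knockout the list did not pass (adjusted p = 0.057). Nor did the stress keratin list with quantile normalization (median -0.54 against -0.94, 11 lower, adjusted p = 0.14). Of the late cornified envelope genes 8 of 20 were lower (6 adjusted over the list alone; -0.56; adjusted p = 0.027, and adjusted p = 0.72 with an estimated correlation), and that list did not pass without MC903 replicate 3 labelled knockout (-0.31, adjusted p = 0.21) or with quantile normalization (-0.22, 2 lower, adjusted p = 0.29). The antimicrobial Defb3 was higher, at 122 ± 26.6 against 25.2 ± 5.57. Krt77 was 10-fold lower, and the neurotrophic factor Nrtn stood at 26.5 ± 5.04 against 102 ± 4.13 (-1.93 ± 0.23, limma adjusted p = 5.4e-05). Very short genes were among the largest differences, such as Mir133a-2, with an annotated length of 104 bp, and Trbd1, of 12 bp, and their FPKM values are uncertain. Scaling to TPM moved the median of all genes by 0.27 and left 73.7% of the called genes higher, against 49.8% as deposited.

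**Figure D2:**
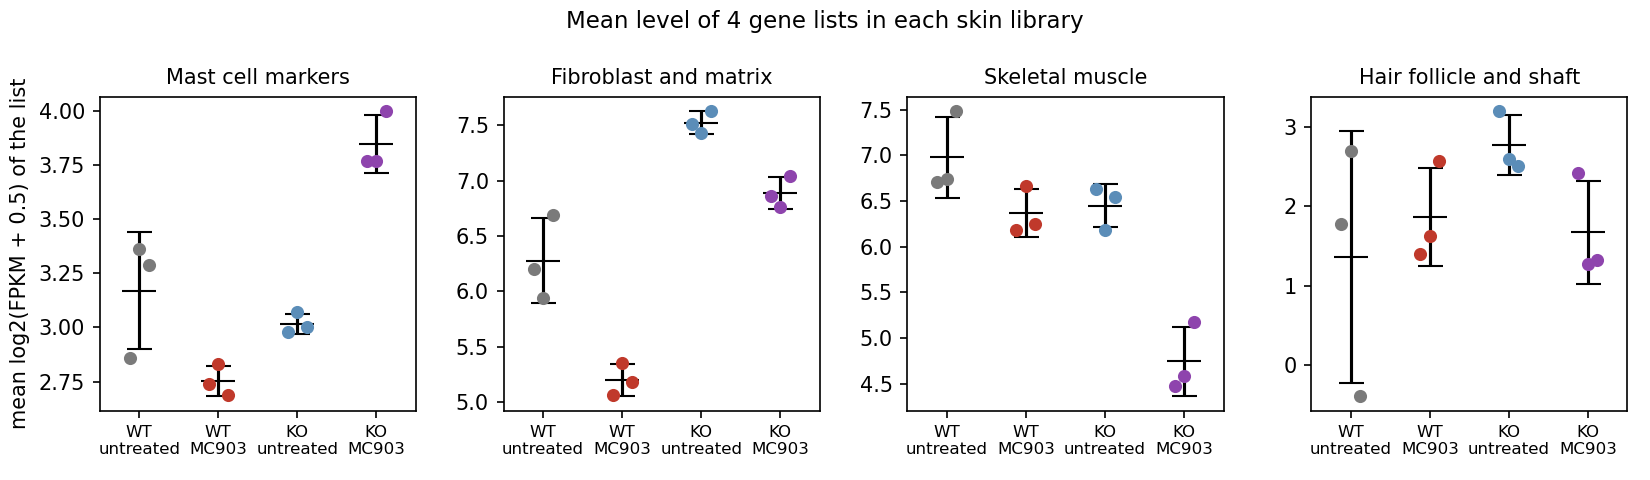
Mean log2(FPKM + 0.5) of the mast cell, fibroblast and matrix, skeletal muscle and hair lists (vertical axes, not starting at 0 and each with a scale of its own) in the 4 groups; points are the 3 libraries of a group, horizontal lines the mean and error bars the SD. After MC903 the mast cell list lies at 3.77 to 4 in libraries labelled knockout and at 2.69 to 2.83 in wild type, and the hair list is lowest (-0.39) in untreated wild type replicate 3.

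The difference of the MC903 response between genotypes was tested directly as an interaction. Positive values mean a response that was more positive in skin labelled knockout. It passed for 7008 genes, 3527 positive and 3481 negative, 2831 of them by at least 2-fold. Trpv3 (-2.06 ± 0.32, limma adjusted p = 0.00063) and F2rl1 (-1.41 ± 0.29, limma adjusted p = 0.0034) had the smaller or opposite response in skin labelled knockout. Il1rl1 had the larger (1.23 ± 0.3, limma adjusted p = 0.0075), while Il33 (0.26 ± 0.26, limma adjusted p = 0.47) and Tslp (0.18 ± 0.47, limma adjusted p = 0.79) did not pass. The largest positive differences included Prss34 (3.85 ± 0.29, limma adjusted p = 3.1e-05), Fcer1a (2.79 ± 0.34, limma adjusted p = 0.00018) and the natriuretic peptide convertase Corin (2.91 ± 0.16, limma adjusted p = 1.4e-05). The largest negative ones included Krt16 (-4.14 ± 0.72, limma adjusted p = 0.0012), Il1f6 (-3.9 ± 0.51, limma adjusted p = 0.00028) and the epithelial gasdermin Gsdmc (-4.18 ± 0.31, limma adjusted p = 3.1e-05). Gsdmc went from 0.339 ± 0.3 to 136 ± 16.2 in wild type and from 2.66 ± 0.113 to 29.2 ± 5.63 in skin labelled knockout.

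In the interaction 9 of 13 mast cell markers were positive (median 1.23), such as Kit (1.62 ± 0.18, limma adjusted p = 0.00012), which fell in wild type and rose in skin labelled knockout, from 3.82 ± 0.0605 to 5.41 ± 0.353, the rise ending with TPM and without MC903 replicate 2 labelled knockout (limma adjusted p of up to 0.14). Positive were also 5 of 6 basophil markers (2.04), 8 of 13 monocyte and macrophage markers (1.15), 9 of 10 Schwann cell and nerve markers (10 adjusted over the list alone; 1.18) and 10 of 13 mitochondrially encoded genes (1.26). Negative were 18 of 21 terminal differentiation genes (21 adjusted over the list alone; -2.17), 19 of 20 late cornified envelope genes (-1.65) and 20 of 27 stress keratin and inflamed-epidermis genes (21 adjusted over the list alone; -2.17). So were 10 of 13 proteases and inhibitors (-1.72) and 15 of 24 cell cycle genes (-0.8). Preset adjusted p-values of these 10 lists were 3.4e-05, 6.1e-05, 0.002, 2e-06, 3.5e-05, 4.5e-08, 1.7e-07, 1.9e-07, 6.1e-05 and 6.1e-05, against adjusted p-values of 0.46, 0.22, 0.46, 0.05, 0.46, 0.46, 0.46, 0.46, 0.46 and 0.51 with an estimated correlation. Of 10 mast cell attractants and growth factors 4 were positive, among them Cxcl12 (1.38 ± 0.17, limma adjusted p = 0.00021) and the Kit ligand Kitl (1.15 ± 0.21, limma adjusted p = 0.0018). That list did not pass (adjusted p = 0.3). Between genotypes in untreated skin the lists with negative differences had medians of 1.23, 1.27, 1.45, 0.99 and 0.3, in the order given. In MC903 skin the medians of these lists were -0.93, -0.56, -0.94, -0.78 and -0.41. Their negative differences thus came in part from higher levels in untreated skin labelled knockout, the least stable comparison. Scaling to TPM moved the median of all genes by 0.26 and left 72.2% of the called genes positive, against 50.3% as deposited. Scaling by total reads moved it by 0.12 and left 61.9% positive.

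**Figure D3:**
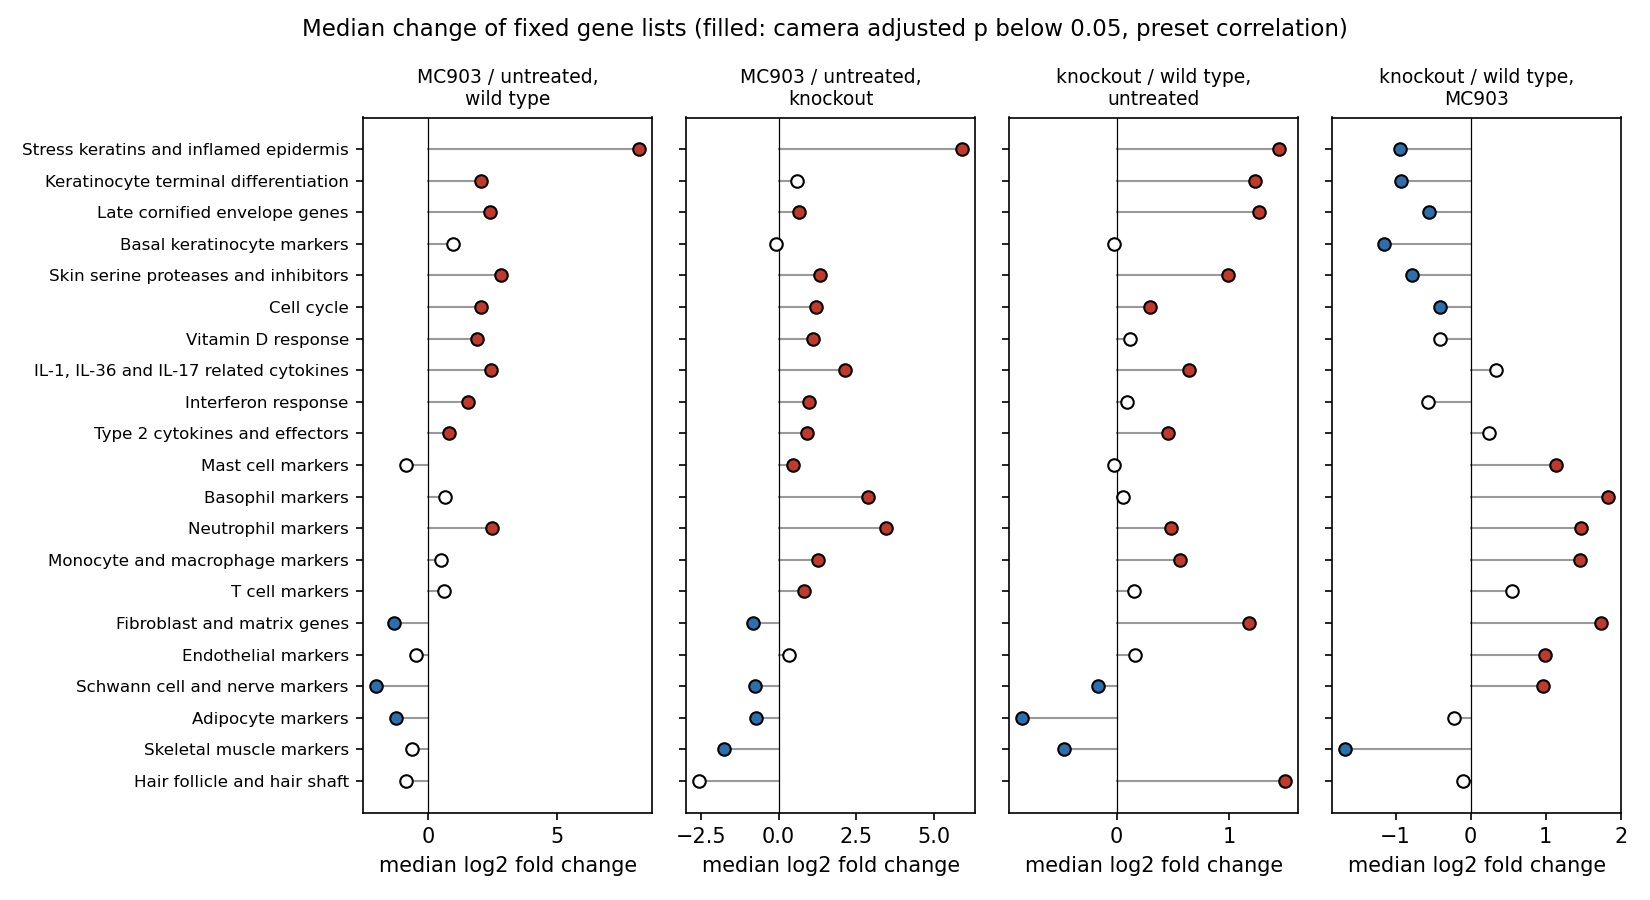
Median log2 fold change (horizontal axes, with a scale of their own in each panel) of gene lists fixed before the data were examined; filled symbols passed the camera test with a preset correlation at an adjusted p below 0.05. The stress keratin list has medians of 8.21 in wild type and 5.89 in skin labelled knockout after MC903, and the mast cell list is 1.13 higher in skin labelled knockout than in wild type after MC903.

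The size of the whole response was compared over the 11492 genes whose mean MC903 effect over both genotypes passed. Counting changes in the direction of that mean effect, the average gene moved by 0.95 on the log2 scale in wild type and by 0.65 in skin labelled knockout, which is 68%, a difference of -0.31. Library scores were 0.95 ± 0.03 (SD, n = 3) in MC903 wild type, 0.72 ± 0.06 in MC903 skin labelled knockout and 0.07 ± 0.03 in untreated skin labelled knockout, on a scale where the untreated wild type mean is 0. All 3 libraries of each group lay apart from those of the other genotype, both treated and untreated, which gives p = 0.1 in an exact two-sided permutation test, the smallest p that 20 assignments of 3 against 3 can give. Of the 11492 genes 59.6% had a smaller response of the same sign in skin labelled knockout, and a further 1382 genes had responses of opposite sign. Across the 17646 genes, which are not independent replicates, the responses of the genotypes correlated with a Pearson r of 0.66 and a Spearman rho of 0.55. Both genotypes raised 2862 of the same genes, where independent lists would share 1438, and lowered 2581, where they would share 1228. In opposite directions, 393 genes rose in wild type and fell in skin labelled knockout, and 338 fell in wild type and rose there.

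**Figure D4:**
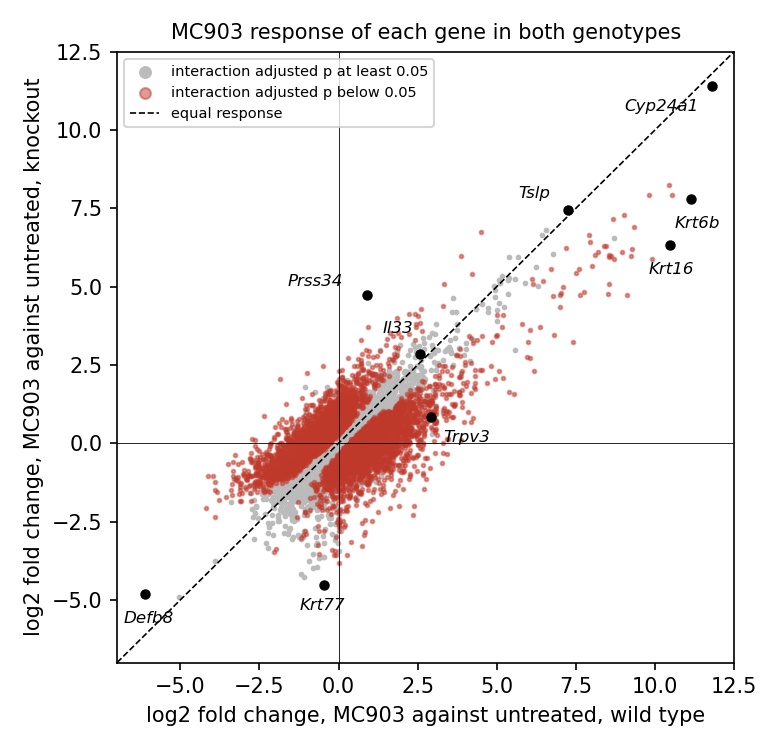
Log2 fold change of MC903 against untreated skin in wild type (horizontal axis) and in skin labelled knockout (vertical axis), on the log2(FPKM + 0.5) scale; each point is 1 of 17646 genes, and red points are the 7008 with an interaction adjusted p below 0.05. Krt16 and Krt6b lie below the dashed line of equal response, and Prss34 above it.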

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

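The tests of mast cell and dermal RNA and the test of intronic genes were chosen only after those results had been seen, whereas the tests of regrouped libraries, host genes and hair genes were written down before their results.

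The MC903 response differed between genotypes for 7008 genes. Splitting the untreated and the MC903 libraries each into other sets of 3 gave a count as large in 2 of 100 splits, the real one being 1 of them, and the highest other split gave 7066. That split exchanged the genotype labels of all 6 MC903 libraries, which adds the genotype differences of treated and untreated skin in place of subtracting them, and the next highest gave 5702. The splits mix genotypes within each treatment, so they bear on any genotype difference and not only on a difference of response. For gene lists a count as large as the real 20 came up in 4 of 100 splits, with a highest other split of 21. For single comparisons 1 of 10 splits, the real one, gave a count of genes as large, against highest other counts of 2 for MC903 in wild type (real 11109), 0 for MC903 in skin labelled knockout (8457), 3 for genotype in untreated skin (2064) and 3 for genotype in MC903 skin (9187). List counts as large were given by 3 splits for MC903 in wild type (real 17, highest other 21), 2 in skin labelled knockout (21 and 22), 1 for genotype in untreated skin (21 and 18) and 6 for genotype in MC903 skin (18 and 23). With 3 against 3 libraries the splits are too few for a share under 0.05.

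The differences of response, knockout-labelled minus wild type, were -2.06 for Trpv3, -1.41 for F2rl1 and 1.23 for Il1rl1. Among the largest positive ones were Cd300ld4 (3.91), Prss34 (3.85), Mest (3.24), Ppbp (3.23), Myoc (3.07), Corin (2.91), Omd (2.88), Lep (2.85), Timp3 (2.82) and Fcer1a (2.79). Among the largest negative ones were Mir133a-1 (-4.62), Trbj2-7 (-4.38), Stfa3 (-4.38), Gsdmc (-4.18), Krt16 (-4.14), Krt77 (-4.06), Sprr2d (-4.02), Serpinb3a (-3.97), Krtap3-3 (-3.91) and Il1f6 (-3.9). Mir133a-1 and Trbj2-7 are very short genes, and Stfa3, Sprr2d and Krtap3-3 share reads with near-identical copies, so their values are uncertain.

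Of the gene lists that passed for this difference, the medians were negative for terminal differentiation (-2.17), stress keratins (-2.17), keratin-associated proteins (-2.06), proteases (-1.72), hair (-1.68), late cornified envelope (-1.65), basal keratinocytes (-1.16), immediate early and heat shock genes (-1.13), skeletal muscle (-1.04), cell cycle (-0.8) and EGFR ligands and growth factor genes (-0.72). They were positive for erythrocytes (2.32), basophils (2.04), mitochondrially encoded genes (1.26), mast cells (1.23), Schwann cells (1.18), macrophages (1.15), neutrophils (1.08), endothelium (0.68) and adipocytes (0.5). None of these lists passed with an estimated correlation, where their adjusted p-values ran from 0.05 to 0.7. Without untreated wild type replicate 3 the calls of the hair (median -0.67, adjusted p = 0.3), keratin-associated protein (0.18), adipocyte (0.18), neutrophil (0.078), EGFR ligand, endothelial and erythrocyte lists (each 0.051) ended.

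Mast cell markers were higher in MC903 skin labelled knockout together with markers of other immune and dermal cells. If a smaller share of epidermal RNA were the whole cause, every other cell type would be higher. The lowest median among 10 lists of non-epidermal cell types, the mast cell list included, was -1.67, that of skeletal muscle. That share alone therefore does not account for the muscle list. The muscle value was known when the test was chosen, and it leaves open whether that share raised the mast cell and dermal lists. The mast cell list minus the fibroblast, endothelial and Schwann cell lists was -0.56 in MC903 skin labelled knockout and -0.47 in wild type, a difference of -0.08, but the fibroblast list that enters it was already higher in untreated skin labelled knockout (median 1.18), where the same value lay between -1.83 and -1.65, against -1.46 to -0.89 in untreated wild type, so its rise with MC903 was the larger in skin labelled knockout. The mast cell median was at least 1.12 under 4 other scalings. In this comparison these moved the median of all genes by 0 to 0.27, none of them downward. They could thus hardly have lowered the mast cell median and do not decide whether scaling is the cause. Whether mast cell RNA rose beyond that of other dermal cells therefore stays open, as does an effect of genotype on cell numbers, since RNA of whole skin does not count cells and the erythrocyte list was higher as well (median 1.78).

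Of 143 small nucleolar RNA genes 42 were lower and 2 higher in MC903 skin labelled knockout than in wild type (median -0.66), where 4612 of all 17646 genes were lower and 4575 higher, and no list test was made of them. More unspliced RNA in the wild type MC903 libraries is a possible explanation, because 44 genes annotated as sense intronic had a median of -0.51. Between MC903 and untreated wild type skin, however, the sense intronic genes moved little (median 0.16, 11 higher and 7 lower). The small nucleolar RNA genes had a median of 0.85 there, with 47 higher and 4 lower. Other noncoding classes moved the same way, with 35 of 203 miRNA genes lower and 3 higher (-0.7), 151 of 509 antisense genes lower and 35 higher (-0.38) and 152 of 506 lincRNA genes lower and 58 higher (-0.24), so the shift was not particular to small nucleolar RNA and its cause stays open. The median of the host genes was -0.16, but a measured host gene was found for only 113 of the 143, so this check is void and host gene RNA stays open.

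The hair list had a median of 1.5 in untreated skin labelled knockout against wild type, with 2 of 28 genes higher, and its call was lost with an estimated correlation (adjusted p = 0.59). Without untreated wild type replicate 3 the median was 0.51 and the list did not pass (adjusted p = 0.4). A low share of hair follicle RNA in that library is a candidate explanation, with a mean list level of -0.39 against 1.77 and 2.7 in the other replicates.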

How the results depend on the processing

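Replicate numbers did not pair libraries across groups, and with a replicate block 11176, 8471, 2124, 9304 and 7046 genes passed for MC903 in wild type, MC903 in skin labelled knockout, genotype in untreated skin, genotype in MC903 skin and the difference of response. Requiring a 2-fold change as well left 4200, 2283, 441, 2489 and 2831. Genotype in untreated skin was the least stable, with 6548 genes under library weights, 613 when only its groups were fitted, 1149 and 3562 without untreated wild type replicates 2 and 3, and 831, 752 and 1176 without untreated replicates 1, 2 and 3 labelled knockout. Leaving out single libraries gave 10169 to 11230, 6784 to 9292, 7889 to 9978 and 5773 to 8003 for the other results in the same order. The difference in size of response (-0.31) was -0.37 with a pseudocount of 0.1, -0.27 with a pseudocount of 1, -0.28 with quantile normalization, -0.4 with TPM and -0.35 without wild type MC903 replicate 2 or without MC903 replicate 2 labelled knockout, and single libraries moved it between -0.35 and -0.29. With an estimated correlation 1, 0, 0, 0 and 0 lists passed, and leaving out single libraries gave 16 to 19, 20 to 24, 13 to 23, 15 to 19 and 13 to 22 lists, with both values of 13 reached without untreated wild type replicate 3. Without that library the calls of the type 2 (adjusted p = 0.087), eosinophil (0.096), neutrophil (0.073), EGFR (0.13), cell cycle (0.26), hair (0.4), keratin-associated protein (0.15) and muscle (0.11) lists in untreated skin ended. With scaling by total reads, chosen after seeing the data, 40%, 45.2%, 49.7%, 57.4% and 61.9% of the genes that passed were higher, against 51.8%, 52.1%, 61.1%, 49.8% and 50.3%; with TPM 26.7%, 33.5%, 66.8%, 73.7% and 72.2% were, and with quantile normalization 46%, 48.5%, 48.6%, 51.6% and 56.4%. A fit of protein-coding genes of at least 200 bp was also chosen after seeing the data. Each named gene was refitted in the comparisons for which the texts name it, and the estimates whose sign turned there had not passed. Il1rl1 after MC903 in wild type was -0.25 with TPM, -0.01 with scaling by total reads and -0.05 to 0.35 when single libraries were left out, and between genotypes in untreated skin it was -0.01 with quantile normalization, -0.01 with scaling by total reads and -0.11 to 0.23 when single libraries were left out. Il1rap after MC903 in wild type was -0.27 with TPM and -0.02 with scaling by total reads, Ddx3y after MC903 in skin labelled knockout -0.03 with TPM, and the difference of response of Tslp -0.04 to 0.61 when single libraries were left out. Except where a changed threshold, scaling or correlation is itself the change, the cause was not tested.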

Other observations

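Cartilage genes, a list put together after the data were seen, were present in all groups and fell with MC903. In wild type 15 of 17 fell (median -2.16; adjusted p = 2.1e-06, and adjusted p = 0.41 with an estimated correlation) and in skin labelled knockout 14 (15 adjusted over the list alone; -1.55; adjusted p = 2.1e-06, and adjusted p = 0.38 with an estimated correlation). Acan, the main proteoglycan of cartilage, went from 103 ± 23 to 13.1 ± 0.402 FPKM in wild type and from 119 ± 8.94 to 52 ± 2.68 in skin labelled knockout. In untreated skin labelled knockout 5 of 17 were higher than in wild type (9 adjusted over the list alone; 0.72; adjusted p = 0.0021, and adjusted p = 0.57 with an estimated correlation). After MC903 15 of 17 were higher (1.27; adjusted p = 2.2e-05, and adjusted p = 0.5 with an estimated correlation). The labels do not name the body site.

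Single genes separated the wild type MC903 libraries from all others. The long noncoding RNA Neat1 stood at 125 ± 21.2 there and at 15.6 ± 1.37 in MC903 skin labelled knockout (-2.95 ± 0.16, limma adjusted p = 1.1e-06). Gapdh, often used as a reference gene, differed between genotypes after MC903 (-3.46 ± 0.72, limma adjusted p = 0.0022), with 68.1, 4.17 and 34.4 FPKM in the wild type MC903 libraries. It has many near-identical copies in the genome that share its reads, so its level is uncertain. Between untreated and MC903 skin the genotype differences overlapped, with 495 genes higher in both where independent lists would share 327, and 238 lower in both where they would share 210. In opposite directions, 384 genes were higher in untreated and lower in MC903 skin labelled knockout where independent lists would share 330, and 169 were lower and then higher where they would share 208.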
